A study of Mus musculus with 21 samples.

How the data were processed

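Mouse aortic valves, 21 samples in all, were lysed directly for RNA, which was purified with the Qiagen RNeasy Micro kit and amplified into libraries with the NuGEN Ovation RNA-Seq System V2, per the labels' protocols. The submitters' processing notes name FastQC, HISAT2, SAMtools and Picard and the mouse genome build mm9. Their versions, the counting program, the annotation and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be separated. The authors deposited 1 table for the series with 20872 genes and the FPKM of each library, that is fragments scaled by gene length and by the mapped fragments of the library, per the file headers. The table also holds the authors' mean FPKM for each of the 5 groups, which was not used beyond a check that it equals the mean of the columns, and 5 columns in which the authors marked changed genes with 0 or 1 by a test that is not given in the sources used here.

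Groups come from the sample titles and descriptions: WT (healthy valve, solvent, n = 4), N1het healthy (solvent, n = 6), N1het healthy XCT790 (n = 5), N1het stenosis (solvent, n = 3) and N1het stenosis XCT790 (n = 3). In 6 of the 21 libraries another label field, the agent, contradicts the title and description: N1het healthy XCT790 1, 2 and 3 carry solvent there, and N1het stenosis 1, 2 and 3 carry XCT790. The column names of the table follow the titles. The labels do not say that libraries of a group are separate animals, so each p measures the spread between samples. Sex was no covariate, because the Y-linked Ddx3y was present in every library (11.3 to 24.7 FPKM). Terc is not listed in the table.

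Each nonzero FPKM of a gene is a whole multiple of a step that differs between genes and libraries, and whole reads were recovered from that step. All nonzero values came out whole within 0.01 reads, and the recovered reads made up 99.97% to 99.99% of each total the steps give. Totals ran from 8.4 to 27.3 megareads (M reads) per library. The median was 13.7 M, and 12.2% to 26.7% of genes stood at 0 in a library, so a low level is measured less exactly in the smaller libraries. Amplified reads without molecular identifiers are not independent molecules. The table holds FPKM, so the test planned for normalized values replaced the planned count tests. The deposited FPKM scale served as it stands. The filter by counts per library size (CPM) used the recovered reads.

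Expression was tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(FPKM + 1) of the 14966 genes with a mean FPKM of 1 or more, which left out 5906. A model of 5 group means was fitted to all 21 libraries, with moderated variances that follow the mean level and resist extreme genes. Within each of 9 contrasts, p was adjusted by Benjamini and Hochberg, and genes under 0.05 were called. Log2 differences are given with their standard error (SE), FPKM with the standard deviation (SD). An effect averaged over healthy and stenotic valves and an interaction complete the contrasts. Sets of genes were tested with camera on the same matrix, with a preset correlation of 0.01 between genes and again with an estimated one, and with limma's fry. Of 41 lists of pathway, response and cell type genes fixed before the data were examined, 40 had 3 or more tested members. They hold 907 genes, of which 869 were listed, 13 of them matched by identifier, and 774 tested. Adjusted p of lists is over the 40 lists of a contrast. With an estimated correlation the number of lists called was 0 in each contrast. The mean of a list was compared between groups by exact permutation of the libraries, two-sided.

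Genes named in the text follow a rule fixed before the data were examined. It takes Notch1, Terc and Esrra. It takes up to 10 called genes with the largest change in each direction that have a mean log2 CPM of 1 or more and whose libraries lie beyond the other group's median. Where fewer than 5 passed in a direction it takes the 5 with the smallest p. It also takes up to 4 members with the smallest p from each called list and 3 of the highest level from marker lists. Symbols that are only model names were passed over, in the smallest-p part too. Descriptions of gene function are general background.

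Each step was first tested on simulated data with the spread of these libraries and 200 of 14966 genes changed. For stenosis against healthy N1het valves the limma test recovered 7.46% of 2-fold, 31.3% of 4-fold and 57.6% of 8-fold changes with 6 false calls, and for XCT790 in stenotic valves 1.49%, 23.9% and 47% with 6. A shifted list of 25 genes at 2-fold was called in each simulated contrast, and 0 of 39 unshifted lists.

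Alternatives covered the pseudocount (0.1), filters on low values, an adjusted p under 0.1, median-of-ratios and upper-quartile scaling of the FPKM, muscle marker levels as covariates, only the compared groups, a block by replicate number, the contradicting label field, limma's voom with sample quality weights on the recovered reads, and leaving out each library in turn. Added after the data were seen were voom without weights, FPKM rescaled to reads that are not mitochondrial, the deep batch as a covariate, the 15 other libraries alone, leaving out the 3 libraries farthest from the rest, covariates of fibroblast or heart muscle markers alone, and the list tests with other filters, scaling, pseudocount and agent labels. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures. The reference at hand, not mm9, served only for gene names, so no coordinates are given.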

Results

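Total RNA of mouse aortic valves was profiled in 21 libraries of 5 labelled groups. All mice lacked Terc, the RNA template of telomerase, and belonged to generation 2 of that line. The 4 WT libraries came from healthy valves of solvent-treated mice with an intact Notch1, the gene of a cell surface receptor whose cleaved inner part regulates transcription. The other mice were labelled heterozygous for Notch1 (N1het), with 6 libraries from healthy and 3 from stenotic valves after solvent, and 5 from healthy and 3 from stenotic valves after XCT790. XCT790 is an inverse agonist of ERRα, the nuclear receptor that Esrra encodes and that drives genes of mitochondrial energy metabolism. It was injected at 5 mg/kg/day for 4 weeks from 4 weeks of age. Stenosis is the narrowing of the valve opening.

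The libraries held 8.4 to 27.3 M reads, with a median of 13.7 M. A set of 6 libraries with 17.7 to 27.3 M reads, called the deep batch from here on, had 0.1% to 0.77% of its reads on mitochondrially encoded genes, while the other 15 libraries had 8.4 to 15.6 M reads and 1.15% to 10.13%. The deep batch held 1 WT library, 2 N1het healthy, 2 N1het healthy XCT790 and 1 N1het stenosis XCT790, and 0 N1het stenosis libraries. Over the 21 libraries, log2 depth and log2 mitochondrial percent had a Pearson r of -0.93 and a Spearman rho of -0.93, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. Pearson's r was -0.91 without the 2 libraries farthest from the median depth, -0.84 within the 15 libraries and -0.70 within the deep batch. Markers of heart muscle cells also split the libraries across the groups. Their mean level on the log2 scale was 4.82 or more in WT 4, N1het healthy 2, 5 and 6, N1het healthy XCT790 5, N1het stenosis 2 and N1het stenosis XCT790 1, and 2.89 or less in every other library. Pearson's r between libraries of 1 group, taken across genes, which are not independent replicates, ran from 0.718 to 0.88 with a mean of 0.821, beside a mean of 0.817 between groups.

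**Figure D1:**
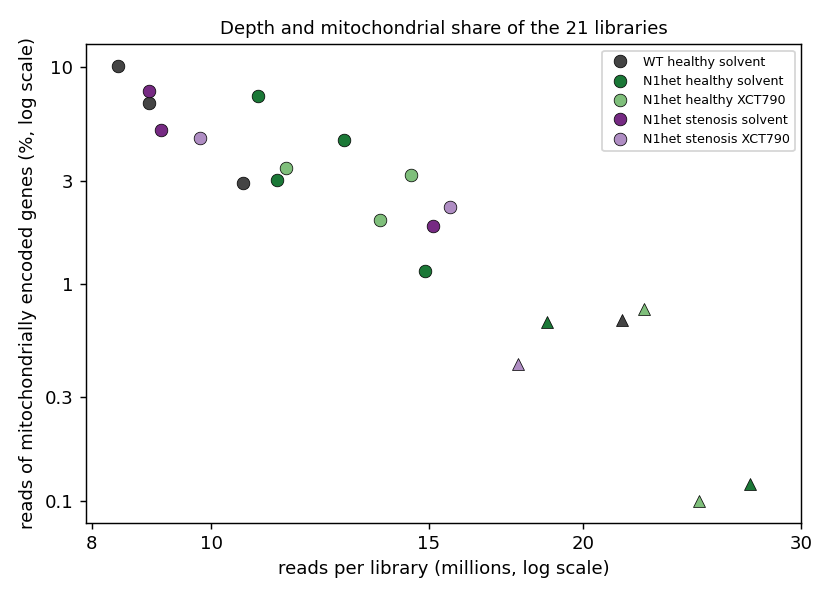
Each point is 1 library, with its reads in M on the x axis and the percent of reads on mitochondrially encoded genes on the y axis, both on log scales, and colours give the 5 groups. The 6 libraries of the deep batch lie at 17.7 M reads or more and at 0.77% or less.

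Notch1 passed the test in no contrast. It stood at 46.5, 33.6, 26.6 and 28.7 FPKM in the 4 WT libraries and at 42.0, 35.6, 50, 28.6, 24.0 and 33.3 FPKM in the 6 N1het healthy libraries. N1het healthy XCT790 libraries had 33.7, 35.9, 29.3, 19.4 and 43.6 FPKM, N1het stenosis 27.0, 26.7 and 20.9, and N1het stenosis XCT790 24.1, 35.6 and 20.9. The log2 difference of N1het healthy from WT was 0.06 ± 0.25 (SE; limma adjusted p = 0.972), and 0.22 within the 15 libraries outside the deep batch. N1het healthy XCT790, N1het stenosis and N1het stenosis XCT790 valves lay at -0.08 ± 0.26, -0.41 ± 0.29 and -0.33 ± 0.29 from WT (adjusted p = 0.97, 0.668 and 0.768). Values per gene can include reads of a mutant allele, so the genotype is taken from the labels alone. Esrra, the gene of the XCT790 target, was low in every library, at 0.364 to 3.46 FPKM. Its log2 difference with XCT790 was 0.29 ± 0.31 in healthy valves (adjusted p = 1) and 0.27 ± 0.42 in stenotic valves (adjusted p = 1).

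Stenotic and healthy N1het valves with solvent by title (n = 3 and 6) differed in 5 single genes and several lists. By the agent label only the stenotic ones had XCT790. Coch, which encodes the matrix protein cochlin, fell from 65.8 ± 30.7 FPKM (SD, n = 6) to 4.16 ± 4.83 (n = 3), a log2 difference of -3.98 ± 0.50 (limma adjusted p = 0.00127). Shisa2, whose product holds back receptors of Wnt and fibroblast growth factors inside the cell, fell from 17.4 ± 6.29 to 1.43 ± 0.979 FPKM, by 2.91 ± 0.40 on the log2 scale (adjusted p = 0.00257). The retinoic acid receptor gene Rara fell from 25 ± 3.87 to 8.2 ± 0.513 FPKM, with a log2 difference of -1.49 ± 0.24 (adjusted p = 0.017), and Isg20l2, a nuclease of ribosomal RNA maturation, from 15.7 ± 4.45 to 2.71 ± 1.12 FPKM, with -2.16 ± 0.36 (adjusted p = 0.0217). Nppb, which encodes the natriuretic peptide BNP, rose from 0.579 ± 0.852 to 26.8 ± 14.1 FPKM, a log2 difference of 4.11 ± 0.73 (adjusted p = 0.0384). In each gene all 3 stenosis libraries lay beyond all 6 healthy ones, which adds no evidence for genes chosen by p in them.

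Among rises that missed the threshold, the smallest p belonged to the leukocyte genes Selplg (log2 difference 2.42 ± 0.46, adjusted p = 0.0656), Itgb2 (2.32 ± 0.49, adjusted p = 0.126) and the lysozyme gene Lyz1 (3.85 ± 0.74, adjusted p = 0.0734), and to the interferon-induced Ifi27l2a (2.10 ± 0.43, adjusted p = 0.126). Among falls, the Polycomb gene Pcgf2 came next (-2.47 ± 0.48, adjusted p = 0.0844).

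The test called 5 of 14966 genes, beside 1437 at an unadjusted p under 0.05 and 748 that chance would give, while limma's voom on the recovered reads called 0 with 1326 at an unadjusted p under 0.05. With sample quality weights voom called 22, of which Rara (adjusted p = 0.0366) and Nppb (0.0386) are among the 5. Shisa2, Coch and Isg20l2 missed the threshold there (0.0508, 0.0705 and 0.0935). Coch and Shisa2 passed with any 1 of the 9 compared libraries left out. Rara missed the threshold without N1het healthy 1 (adjusted p = 0.0526) or N1het stenosis 1, 2 or 3 (0.0708, 0.0735 and 0.201), and Isg20l2 without N1het healthy 1 or 4 (0.0731 and 0.0777) or N1het stenosis 2 or 3 (0.117 and 0.372). Nppb missed it without N1het healthy 1, 2, 3, 4 or 5 (0.112, 0.0703, 0.0572, 0.0947 and 0.0821) and without N1het stenosis 2 or 3 (0.173 and 0.416). It also missed it without the 3 libraries farthest from the rest, WT 1, WT 4 and N1het healthy 3 (0.0562), and with a pseudocount of 0.1 (log2 difference 6 ± 1.44, adjusted p = 0.163). The number called was 2, 3 and 11 without N1het healthy 1, 4 and 6, and 2 without N1het stenosis 2 or 3. Within the 15 libraries outside the deep batch limma called 0 genes with 1105 at an unadjusted p under 0.05, and the log2 differences were -3.80 for Coch, -2.70 for Shisa2, -1.45 for Rara, -1.99 for Isg20l2 and 3.95 for Nppb.

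Markers of macrophages and monocytes were higher in stenotic N1het valves, with the smallest p of any list. All 23 tested members were higher, with a median log2 difference of 1.5 (camera adjusted p = 4.79e-22, and adjusted p = 0.0601 with an estimated correlation), and all 3 stenosis libraries lay above all 6 healthy ones in the mean of the list (exact permutation p = 0.0119, two-sided, the smallest that 84 splits can give). Over all genes tested limma called 0 of the 23, with 20 at an unadjusted p under 0.05, and 20 passed when adjusted over the list alone. The lysozyme gene Lyz2 stood at 822 ± 356 FPKM in healthy and 2860 ± 730 in stenotic valves, a log2 difference of 1.89 ± 0.45. The complement genes C1qa and C1qb had 1.59 ± 0.35 and 1.45 ± 0.38, and the protease gene Ctss 1.87 ± 0.57. The median was 1.36 within the 15 libraries outside the deep batch.

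Interferon-stimulated genes were higher in 28 of 30, with a median of 0.82 (camera adjusted p = 1.78e-08, and adjusted p = 0.282 with an estimated correlation). Ifi35 had a log2 difference of 1.21 ± 0.36. Adjusted over the list alone 0 of the 30 passed, as over all genes tested by limma, with 9 at an unadjusted p under 0.05, and the median was 0.94 within the 15 libraries. Antigen presentation genes were higher in 12 of 16, with a median of 0.72 (camera adjusted p = 0.000789, and adjusted p = 0.393 with an estimated correlation). Its class I members H2-K1 and B2m had 0.99 ± 0.26 and 0.63 ± 0.22, and 3 of the 16 passed adjusted over the list alone against 0 over all genes, with 5 at an unadjusted p under 0.05. The list lost its call without N1het stenosis 3 (median 0.46, adjusted p = 0.158), and its median was 0.71 within the 15 libraries.

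Inflammatory cytokine and adhesion genes were higher in 24 of 30, with a median of 0.76 (camera adjusted p = 0.000148, and adjusted p = 0.189 with an estimated correlation). The monocyte attractants Ccl2 and Ccl7 had log2 differences of 1.75 ± 0.48 and 1.77 ± 0.55. Of the 30 genes, 5 passed adjusted over the list alone, 4 up and 1 down, and 0 over all genes tested by limma, with 7 at an unadjusted p under 0.05. Within the 15 libraries the median was 0.40. Cell cycle genes were higher in 22 of 27, with a median of 0.71 (camera adjusted p = 9.64e-06, and adjusted p = 0.0601 with an estimated correlation). The spindle genes Tpx2 and Kif11 had 2.06 ± 0.47 and 1.29 ± 0.48 and the cyclin-dependent kinase gene Cdc2a 1.81 ± 0.58. Only 1 of the 27 passed adjusted over the list alone and 0 over all genes, with 6 at an unadjusted p under 0.05. The median was 0.45 without N1het stenosis 1 or with the deep batch as a covariate, 1.14 with a pseudocount of 0.1 and 0.55 within the 15 libraries.

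Fibroblast and matrix genes were lower. Markers of valve interstitial cells and fibroblasts were lower in 18 of 19, with a median log2 difference of -0.65 (camera adjusted p = 8.79e-08, and adjusted p = 0.0601 with an estimated correlation). Adjusted over the list alone 8 passed, against 0 over all genes tested by limma and 10 at an unadjusted p under 0.05. The small proteoglycan gene Dcn stood at 4740 ± 638 FPKM in healthy and 2950 ± 317 in stenotic valves (-0.68 ± 0.15), the microfibril gene Mfap4 had -1.48 ± 0.39 and the growth factor receptor gene Pdgfra -1.37 ± 0.36. Within the 15 libraries the median was -0.50. Extracellular matrix genes, 2 of which the fibroblast list also holds, were lower in 24 of 32, with a median of -0.46 (camera adjusted p = 0.000646, and adjusted p = 0.579 with an estimated correlation). The matrix genes Fbln1 and Vcan had -1.28 ± 0.32 and -1.16 ± 0.35, and 5 of the 32 passed adjusted over the list alone against 0 over all genes, with 12 at an unadjusted p under 0.05. The matrix list lost its call without N1het stenosis 1 (median -0.32, adjusted p = 0.139). Its median was -0.28 without N1het healthy 4 and -0.30 with the deep batch as a covariate, and within the 15 libraries it did not pass (median -0.15, adjusted p = 0.22).

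Genes of bone and cartilage formation were lower, not higher, in stenotic than in healthy N1het valves. The osteogenic and mineralization list was lower in 15 of 20, with a median log2 difference of -0.52 (camera adjusted p = 0.02, and adjusted p = 0.189 with an estimated correlation). The homeobox gene Msx1 had -1.31 ± 0.34 and the channel gene Panx3 -2.53 ± 0.69, and 2 of the 20 passed adjusted over the list alone against 0 over all genes tested by limma, with 3 at an unadjusted p under 0.05. The call was lost without N1het healthy 6 (median -0.47, adjusted p = 0.0614) or N1het stenosis 2 (-0.51, adjusted p = 0.126), and within the 15 libraries the median was -0.59 with an adjusted p of 0.0608. Cartilage-type genes were lower in 14 of 18, with a median of -0.57 (camera adjusted p = 0.00201, and adjusted p = 0.291 with an estimated correlation). Sox9, the main transcription factor of cartilage, had -1.25 ± 0.46 and the lubricin gene Prg4 -1.41 ± 0.43. In this list 0 of 18 passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05, and its call was lost without N1het stenosis 1 (median -0.38, adjusted p = 0.09) and within the 15 libraries (median -0.30, adjusted p = 0.0681). Its median was -0.37 without N1het healthy 4 or with the deep batch as a covariate.

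Signs of handling and library quality moved between stenotic and healthy N1het valves too. Immediate early genes, which dissection can induce, were higher in 17 of 21, with a median log2 difference of 0.36 (camera adjusted p = 0.0147, and adjusted p = 0.719 with an estimated correlation), and the cytokine signalling inhibitor gene Socs3 had 0.86 ± 0.32. The call was lost without N1het healthy 4, 5 or 6 (medians 0.31, 0.35 and 0.15, adjusted p = 0.0963, 0.0625 and 0.105), without N1het stenosis 1 or 3 (0.39 and 0.16, adjusted p = 0.0917 and 0.235) and within the 15 libraries (0.25, adjusted p = 0.142). Their median was 0.59 without N1het healthy 3, 0.66 without N1het stenosis 2, and 0.59 without the 3 farthest libraries. Mitochondrially encoded genes were higher in all 6, with a median of 1.59 (camera adjusted p = 0.0333, and adjusted p = 0.725 with an estimated correlation), and the call was lost within the 15 libraries (median 0.27, adjusted p = 0.439) and with the deep batch as a covariate (0.37). It was also lost without N1het healthy 1, 2 or 4 (medians 1.3, 1.52 and 0.81, adjusted p = 0.0847, 0.0671 and 0.338) or N1het stenosis 2 or 3 (1.21 and 1.34, adjusted p = 0.199 and 0.113). Limma called 0 members of both lists over all genes and 0 adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05.

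Stenotic N1het valves were also set against WT valves (n = 3 and 4), which joins genotype, disease and, by the agent label, XCT790. The lysozyme gene Lyz1 rose from 5.42 ± 6.88 FPKM to 129 ± 21.2, a log2 difference of 4.91 ± 0.79 (limma adjusted p = 0.0362). Nceh1, a hydrolase of cholesterol esters, rose from 3.06 ± 1.25 to 16.4 ± 3.1 FPKM (2.14 ± 0.37, adjusted p = 0.0362), and Coch fell from 34.7 ± 13.6 to 4.16 ± 4.83 FPKM (-3.13 ± 0.54, adjusted p = 0.0362). Nppb was listed at 0 in all 4 WT libraries and stood at 26.8 ± 14.1 FPKM in stenosis. Its fitted log2 difference of 4.63 ± 0.79 (adjusted p = 0.0362) depends on the pseudocount (7.89 with 0.1, adjusted p = 0.0612) and is no bound on the fold. BC067068, a transcript of unstated function chosen after its values were seen because it completes the called set, rose from 0.981 ± 0.343 to 10.3 ± 2.5 FPKM (2.50 ± 0.45, adjusted p = 0.0419). In all 5 genes the 3 stenosis libraries lay beyond the 4 WT ones, which again adds no evidence.

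Next to the threshold stood the sterol-regulated Tmem97 (3.23 ± 0.60, adjusted p = 0.0507) and the receptor kinase gene Grk5 (1.5 ± 0.29, adjusted p = 0.0586) with higher values, and the potassium channel subunit gene Abcc9 (-1.59 ± 0.30), the splicing regulator gene Rbm10 (-1.84 ± 0.36, both adjusted p = 0.0586) and the imprinted gene Peg3 (-1.64 ± 0.32, adjusted p = 0.0709) with lower values. Rara had -1.20 ± 0.26 (adjusted p = 0.144).

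The test against WT called 4 genes up and 1 down, beside 1563 genes at an unadjusted p under 0.05. With median-of-ratios scaling of the FPKM the split was 5 up and 4 down. The count was 0 with the heart and smooth muscle marker levels as covariates, with the deep batch as a covariate or with only the compared groups. Voom called 3 genes, among them Nppb (adjusted p = 0.035) and none of the other 4. It called 1 with sample quality weights, which is none of the 5 (0.0691 to 0.384). The count was 2, 0 and 0 without N1het stenosis 1, 2 and 3, and 0, 1, 0 and 3 without WT 1, 2, 3 and 4. Lyz1 passed only without WT 4 (adjusted p = 0.00619) and Coch only without N1het stenosis 1 (0.00296). Without any other of the 7 compared libraries their adjusted p ran from 0.053 to 0.383, and that of Nppb, Nceh1 and BC067068 ran from 0.0528 to 0.365 over all 7 fits. Within the 15 libraries limma called 0 genes with 1320 at an unadjusted p under 0.05, and the log2 differences were 4.98 for Lyz1, 4.63 for Nppb, 2.30 for Nceh1, 2.55 for BC067068 and -3.25 for Coch.

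Against WT, too, macrophage and monocyte markers had the smallest p of any list, with all 23 members higher and a median log2 difference of 1.23 (camera adjusted p = 2.1e-13, and adjusted p = 0.282 with an estimated correlation). Over all genes 1 of them passed, Lyz1, with 15 at an unadjusted p under 0.05, and 8 passed adjusted over the list alone. Lyz2 had a log2 difference of 2.05 ± 0.48, the membrane protein gene Ms4a7 2.33 ± 0.62 and the antibody receptor gene Fcgr1 2.05 ± 0.58, and the median was 1.38 within the 15 libraries. Interferon-stimulated genes were higher in 27 of 30, with a median of 0.66 (camera adjusted p = 0.000297, and adjusted p = 0.68 with an estimated correlation). Irf9, part of the interferon-activated transcription complex, had 1.66 ± 0.50 and Bst2 1.35 ± 0.41, with 0 of 30 past the threshold over all genes by limma or adjusted over the list alone, 5 at an unadjusted p under 0.05 and a median of 0.56 within the 15 libraries. Cell cycle genes were higher in 22 of 27, with a median of 0.79 (camera adjusted p = 0.000887, and adjusted p = 0.282 with an estimated correlation). Tpx2 had 2.16 ± 0.51 and the mitotic kinase gene Aurkb 1.71 ± 0.58. Of these 27 genes 1 passed adjusted over the list alone and 0 over all genes, with 5 at an unadjusted p under 0.05, and the median was 0.44 without the 3 farthest libraries, 1.38 with a pseudocount of 0.1 and 0.78 within the 15 libraries.

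Fibroblast markers were lower than in WT in 16 of 19, with a median log2 difference of -0.47 (camera adjusted p = 7.06e-05, and adjusted p = 0.282 with an estimated correlation). Mfap4 stood at 611 ± 95.8 FPKM in WT and 188 ± 80.7 in stenosis (-1.77 ± 0.42), and Pdgfra had -1.49 ± 0.39. Adjusted over the list alone 4 of the 19 passed, against 0 over all genes by limma and 4 at an unadjusted p under 0.05, and the median was -0.46 within the 15 libraries. The osteogenic, cartilage-type and matrix lists did not pass against WT (medians -0.37, -0.18 and -0.17, camera adjusted p = 0.269, 0.312 and 0.132). Nuclear-encoded genes of oxidative phosphorylation were higher in 43 of 48, with a median of 0.49 (camera adjusted p = 4.74e-05, and adjusted p = 0.68 with an estimated correlation), among them the cytochrome oxidase subunit gene Cox6b1 at 1.39 ± 0.52. With the heart and smooth muscle marker levels as covariates this call was lost (median 0.29, adjusted p = 0.0541), and with the deep batch as a covariate the median was 0.32. Ribosomal protein genes were higher in 38 of 40, with a median of 0.34 (camera adjusted p = 7.06e-05, and adjusted p = 0.766 with an estimated correlation), and Rpl37 had 0.63 ± 0.24. In both lists 0 members passed over all genes by limma or adjusted over the list alone, with 8 and 7 at an unadjusted p under 0.05. The medians of these 2 lists were 0.33 and 0.21 within the 15 libraries. That of the ribosomal list was 0.21 without WT 1 and 0.20 without the 3 farthest libraries.

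**Figure D2:**
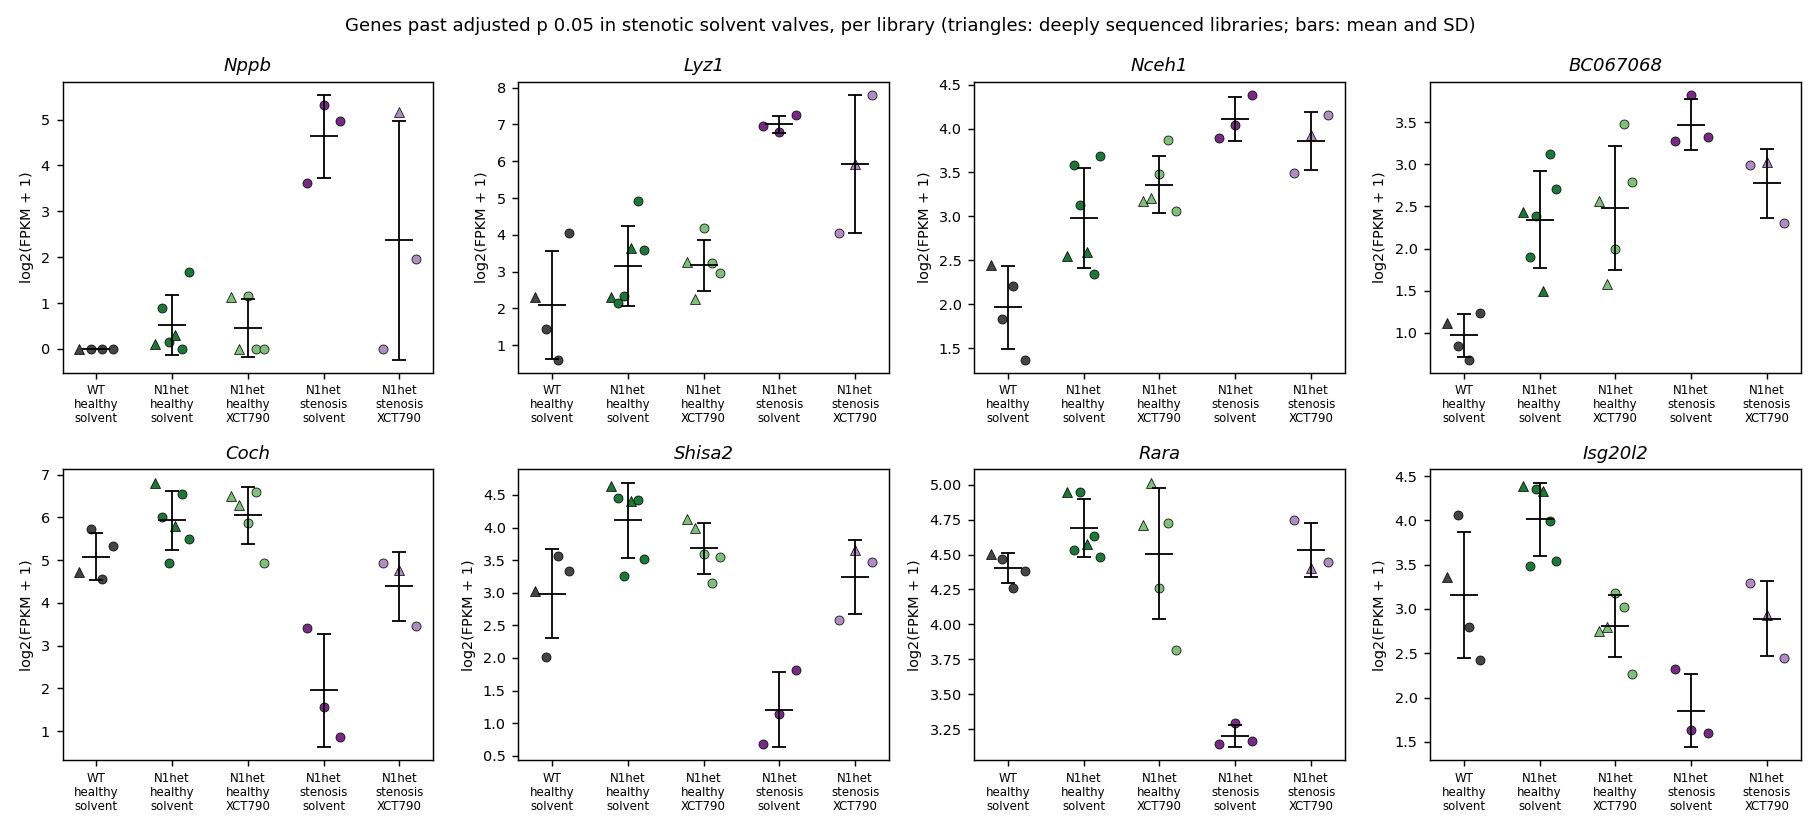
Each panel plots 1 gene called in stenosis against WT or against healthy N1het valves, with log2(FPKM + 1) of each library on the y axis, the 5 groups on the x axis and bars at the mean and 1 SD. Rara lies between 7.84 and 8.79 FPKM in the 3 N1het stenosis libraries and at 18.1 FPKM or more in the WT libraries.

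N1het healthy valves differed from WT valves (n = 6 and 4) in no single gene that passed the test. The gap junction gene Gja4, typical of arterial endothelium, stood at 11.6 ± 3.82 FPKM in WT and 53.4 ± 22.5 in N1het healthy valves (2.08 ± 0.43, adjusted p = 0.294). Values of the same adjusted p were 2.06 ± 0.44 for Kctd15, 1.83 ± 0.38 for the chromatin reader gene Ing5, 1.59 ± 0.34 for the Golgi gene Cog7 and 1.14 ± 0.23 for Zfp869. On the lower side stood Dkc1, the gene of dyskerin, which binds telomerase RNA (-1.66 ± 0.41), the kinase gene Prkcc (-1.94 ± 0.49), Grrp1 (-2.69 ± 0.68), the fatty acid desaturase gene Fads1 (-0.91 ± 0.23) and the cytokine signalling inhibitor gene Socs3 (-1.10 ± 0.29), all with an adjusted p of 0.409. Limma called 0 genes with 1111 at an unadjusted p under 0.05, of which 792 were higher and 319 lower, and voom called 0 with 1337. The count was 1 without WT 2 and 5 without WT 3, and within the 15 libraries it was 0 with 913 at an unadjusted p under 0.05.

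Markers of heart muscle cells were higher in N1het healthy than in WT valves in 30 of 31, with a median log2 difference of 1.5 (camera adjusted p = 0.00304, and adjusted p = 0.785 with an estimated correlation). Myl2, a myosin light chain gene of the ventricle, had 3.08 ± 1.61, Tnnt2 1.76 ± 1.24 and the mitochondrial creatine kinase gene Ckmt2 3.71 ± 1.09. The call was lost without WT 1 (median 1.16, adjusted p = 0.123), WT 2 (1, 0.176), N1het healthy 2 (0.92, 0.0673) or N1het healthy 6 (1.05, 0.106). The median was 2.30 without WT 4 and 2.53 without the 3 farthest libraries, and it was 2.03 within the 15 libraries. Nuclear-encoded oxidative phosphorylation genes were higher in 40 of 48, with a median of 0.35 (camera adjusted p = 0.00215, and adjusted p = 0.785 with an estimated correlation). Atp5o and Ndufv2 had 1.06 ± 0.33 and 1.05 ± 0.33, and the median was 0.49 within the 15 libraries. With the heart and smooth muscle marker levels as covariates the call was lost (median -0.06, adjusted p = 0.548), as it was without WT 1 (0.23, adjusted p = 0.134), N1het healthy 2 (0.25, 0.0546) or N1het healthy 6 (0.23, 0.0816). Fatty acid oxidation genes were higher in 20 of 25, with a median of 0.44 (camera adjusted p = 0.0157, and adjusted p = 0.785 with an estimated correlation), with Acadvl at 1.16 ± 0.31 and Cpt2 at 1.31 ± 0.42. That call was lost with the same covariates (median 0.07, adjusted p = 0.843) and without WT 1 (0.27, adjusted p = 0.14), WT 2 (0.49, 0.0517), N1het healthy 2 (0.30, 0.0966) or N1het healthy 6 (0.30, 0.106). The median was 0.41 within the 15 libraries. Over all genes limma called 0 members of the 3 lists, with 1, 7 and 4 at an unadjusted p under 0.05, and adjusted over the list alone 0, 0 and 1 passed. In 6 libraries the agent label contradicts the title, and with groups by that label the 3 calls were lost (medians 0.80, 0.23 and 0.23, adjusted p = 0.267, 0.072 and 0.202).

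Smooth muscle markers were lower in N1het healthy than in WT valves in 12 of 17, with a median of -0.57 (camera adjusted p = 0.0157, and adjusted p = 0.785 with an estimated correlation). The smooth muscle myosin gene Myh11 had -3.30 ± 1.66, and 0 of 17 members passed over all genes by limma or adjusted over the list alone, with 1 at an unadjusted p under 0.05. The list's call was lost without WT 4 (median -0.17, adjusted p = 0.901) or the 3 farthest libraries (-0.26, adjusted p = 0.686) and with groups by the agent label (-0.41, adjusted p = 0.072). Its median was -1 without WT 1, and it was -1.06 within the 15 libraries. Mitochondrially encoded genes were lower than in WT in all 6, with a median of -1.19 (camera adjusted p = 0.0438, and adjusted p = 0.785 with an estimated correlation) and 0 members at an unadjusted p under 0.05. Their call was lost without WT 2, 3 or 4 (medians -1.33, -0.88 and -0.72, adjusted p = 0.0517, 0.281 and 0.37) or N1het healthy 1, 2 or 4 (-1.01, -1.13 and -0.54, adjusted p = 0.108, 0.0921 and 0.394) and with FPKM rescaled to reads that are not mitochondrial, median-of-ratios or upper-quartile scaling or no filter (adjusted p = 0.0653, 0.0872, 0.0555 and 0.051). The median was -2.06 without WT 1, -1.84 without the 3 farthest libraries and -2.07 with the muscle marker covariates. The Notch pathway list did not pass, with 12 of its 28 genes higher, 16 lower and a median of -0.12 (camera adjusted p = 0.305).

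For XCT790 in N1het valves labelled healthy (n = 5, against 6 with solvent), no gene passed. The leukocyte integrin gene Itgb2 stood at 5.87 ± 3.7 FPKM with solvent and 22.5 ± 6.35 with XCT790 (1.91 ± 0.42), and the phosphatase gene Ptpn6 and Ddrgk1 had log2 differences of 1.60 ± 0.45 and 0.83 ± 0.21. Isg20l2 stood at 15.7 ± 4.45 with solvent and 6.14 ± 1.62 with XCT790 (-1.21 ± 0.31), Unkl had -1.47 ± 0.39, the peptide-activating protease gene Corin -0.94 ± 0.49 and Ckmt2 -3.46 ± 1.02, each with an adjusted p of 1. Limma called 0 genes with 397 at an unadjusted p under 0.05, fewer than the 748 that chance would give, and voom called 0 with 462. Within the 15 libraries the count was 0 with 713.

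Heart muscle markers were lower with XCT790 in all 31 genes, with a median log2 difference of -1.01 (camera adjusted p = 2.34e-06, and adjusted p = 0.667 with an estimated correlation). The median was -0.57 without N1het healthy 2 or N1het healthy 6 and -1.57 without N1het healthy XCT790 5, and it was -1.44 within the 15 libraries. Genes of oxidative metabolism, which ERRα drives, were lower as well. In the oxidative phosphorylation list 36 of 48 were lower, with a median of -0.23 (camera adjusted p = 0.000104, and adjusted p = 0.669 with an estimated correlation), among them Ndufb9 at -0.48 ± 0.22 and Sdhb at -0.62 ± 0.32. The median of this list was -0.38 without N1het healthy 1, -0.12 without N1het healthy 2, -0.13 without N1het healthy 6 and -0.15 without N1het healthy XCT790 2. It was -0.27 within the 15 libraries, and with the heart muscle and smooth muscle marker levels as covariates it turned to 0.05 (adjusted p = 0.645). Fatty acid oxidation genes were lower in 22 of 25, with a median of -0.22 (camera adjusted p = 0.000321, and adjusted p = 0.64 with an estimated correlation). Lpl, the lipase that frees fatty acids from lipoproteins, had -0.85 ± 0.47 and the carnitine transferase gene Cpt1b -1.20 ± 0.68. With the same covariates this call was lost too (median -0.03, adjusted p = 0.48). The median was -0.42 without N1het healthy 3, -0.35 without N1het healthy 4, -0.42 without the 3 farthest libraries and -0.33 within the 15 libraries. Limma called 0 members of the 3 lists over all genes and 0 adjusted over the list alone, with 1, 2 and 0 at an unadjusted p under 0.05. Without the 6 libraries with contradicting labels, which leaves 2 treated libraries here, the 3 calls were lost (medians 0.02, -0.02 and -0.08, adjusted p = 0.841, 0.614 and 0.51). They were also lost with groups by the agent label (0.58, 0.06 and 0, adjusted p = 0.177, 0.542 and 0.788). The list of ERR and PGC-1 genes itself did not pass (median -0.06, camera adjusted p = 0.794).

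Macrophage markers were higher with XCT790 in healthy N1het valves in 22 of 23, with a median log2 difference of 0.54 (camera adjusted p = 3.64e-06, and adjusted p = 0.64 with an estimated correlation). The chemokine receptor genes Ccr2 and Cx3cr1 had 1.74 ± 0.58 and 0.99 ± 0.43 and C1qb 0.78 ± 0.33. The median was 0.30 without N1het healthy 4, 0.32 without N1het healthy XCT790 5, 0.97 with the muscle marker covariates, 1.19 without the 6 libraries with contradicting labels, 1.13 with groups by the agent label and 0.81 within the 15 libraries. Antigen presentation genes were higher in 15 of 16, with a median of 0.50 (camera adjusted p = 0.000268, and adjusted p = 0.64 with an estimated correlation), among them the class II genes H2-Eb1 and H2-Aa at 1.06 ± 0.41 and 0.98 ± 0.39. This call was lost without N1het healthy XCT790 5 (median 0.18, adjusted p = 0.125), the median was 0.31 without N1het healthy 6, and it was 0.54 within the 15 libraries. Endothelial markers were lower in 20 of 24, with a median of -0.42 (camera adjusted p = 0.000587, and adjusted p = 0.667 with an estimated correlation), and the surface protein gene Emcn had -0.85 ± 0.42. They lost the call with the muscle marker covariates (median -0.22, adjusted p = 0.101), without N1het healthy 3 (-0.22, adjusted p = 0.128) without the 3 farthest libraries (-0.22, adjusted p = 0.148) and with groups by the agent label (-0.39, adjusted p = 0.108). The median was -0.22 without N1het healthy XCT790 4 and -0.76 within the 15 libraries. Limma called 0 members of these 3 lists over all genes and 0 adjusted over the list alone, with 5, 3 and 0 at an unadjusted p under 0.05.

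For XCT790 in stenotic N1het valves (n = 3 and 3), no gene passed. By the agent label both groups had XCT790. The labels do not say whether stenosis came before treatment, so in every XCT790 contrast the compound may affect which valves are healthy or stenotic. The 3 solvent libraries also enter stenosis against WT or healthy valves, so genes low in them should be higher here without any effect. Across all genes the effect of XCT790 had an r of -0.49 with that of stenosis over WT, where simulated groups with no effect gave -0.53 (permutation p = 0.350). Rara stood at 8.2 ± 0.513 FPKM with solvent and 22.3 ± 3.18 with XCT790 (1.33 ± 0.28), and Shisa2 at 1.43 ± 0.979 and 8.93 ± 3.47 (2.04 ± 0.46). Rbm10 had 1.69 ± 0.38 and Isoc1 1.68 ± 0.39, each with an adjusted p of 0.765. On the lower side were Mfsd1 (-1.14 ± 0.31), Scamp4 (-4.24 ± 1.17), Rilp (-2.54 ± 0.73), the mitotic gene Cdca3 (-2.02 ± 0.58) and Eef1e1 (-2.17 ± 0.63), each with an adjusted p of 1. Coch was at 4.16 ± 4.83 with solvent and 21.8 ± 10.4 FPKM with XCT790. Limma called 0 genes with 501 at an unadjusted p under 0.05, and voom called 0 with 381. The count was 1 without N1het stenosis 1 or N1het stenosis XCT790 1 and 2 without N1het stenosis XCT790 3, and within the 15 libraries it was 0 with 462.

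Macrophage markers were lower with XCT790 in stenotic valves in 22 of 23, with a median of -0.28 (camera adjusted p = 0.00125, and adjusted p = 0.973 with an estimated correlation). C1qa had -0.78 ± 0.40 and the scavenger receptor gene Cd163 -0.84 ± 0.43. The call was lost without N1het stenosis 3 (median -0.09, adjusted p = 0.188), and without N1het stenosis XCT790 1 the median turned to 0.22 (adjusted p = 0.937). The median was -0.50 without N1het stenosis 2, -0.72 without N1het stenosis XCT790 3, -0.14 with the muscle marker covariates, -0.15 with the deep batch as a covariate and -0.40 within the 15 libraries. Neutrophil and mast cell markers were lower in 8 of 9, with a median of -0.78 (camera adjusted p = 0.00975, and adjusted p = 0.973 with an estimated correlation), and the calcium-binding alarmin genes S100a9 and S100a8 had -2.71 ± 0.82 and -1.26 ± 0.89. That call was lost with the filter by counts per library size or a pseudocount of 0.1 (-0.60 and -0.90, adjusted p = 0.115 and 0.0606), without N1het stenosis 2 (-0.12, adjusted p = 0.423) or N1het stenosis XCT790 1 (-0.96, adjusted p = 0.139). The median was -1.21 without N1het stenosis 1 and -0.85 within the 15 libraries. Limma called 0 members of either list over all genes, with 0 and 1 at an unadjusted p under 0.05, and 0 and 1 adjusted over the list alone.

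Whether the effect of XCT790 differed between stenotic and healthy valves was tested as an interaction, in which limma called 0 genes with 446 at an unadjusted p under 0.05 and voom 0 with 425. Rara (1.51 ± 0.34), Isg20l2 (2.25 ± 0.52), Shisa2 (2.46 ± 0.58), Otud3 (3.40 ± 0.80) and Tpx2 (-2.84 ± 0.68) had the smallest p, each with an adjusted p of 0.974. The solvent libraries enter with the sign opposite to stenosis against healthy valves, which alone can lower genes high there. Macrophage markers were lower in all 23 genes, with a median of -0.78 (camera adjusted p = 4.51e-09, and adjusted p = 0.547 with an estimated correlation). Itgb2, outside that list, had -2.39 ± 0.70 and C1qa -1.42 ± 0.50. The median was -0.34 without N1het stenosis XCT790 1, -1.28 without N1het stenosis XCT790 3 and -1.23 within the 15 libraries. Cell cycle genes were lower in 21 of 27, with a median of -0.40 (camera adjusted p = 0.00202, and adjusted p = 0.547 with an estimated correlation). They lost the call without N1het stenosis XCT790 1 (median -0.46, adjusted p = 0.0698) or 2 (-0.41, 0.0576). The median was -0.20 without N1het healthy 3, -0.60 without N1het healthy 4, -0.63 without N1het stenosis XCT790 3, -0.20 without the 3 farthest libraries, -0.87 with a pseudocount of 0.1 and -0.68 within the 15 libraries. Over all genes limma called 0 members of both lists, with 1 and 2 at an unadjusted p under 0.05, and adjusted over the list alone 0 and 1 passed. The number of genes called in the interaction was 1 without N1het stenosis 1 and 2 without N1het stenosis XCT790 3, and 0 within the 15 libraries with 535 at an unadjusted p under 0.05.

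Averaged over healthy and stenotic valves, the effect of XCT790 passed in 0 genes by limma, with 482 at an unadjusted p under 0.05, and in 0 by voom, with 439. The ephrin gene Efna2 had 1.94 ± 0.45 and the phosphatase gene Cdkn3 -1.84 ± 0.48, both with an adjusted p of 1. Heart muscle markers were lower in 28 of 31, with a median of -0.70 (camera adjusted p = 6.43e-06, and adjusted p = 0.964 with an estimated correlation), with 0 members called over all genes by limma or adjusted over the list alone and 2 at an unadjusted p under 0.05. Their call was lost and the median turned to 0.07 without N1het stenosis 2 (adjusted p = 0.627). It was -1.41 without N1het stenosis 1, -1.16 without N1het stenosis XCT790 1, -0.32 without N1het stenosis XCT790 3 and -0.38 with the deep batch as a covariate. Mitochondrially encoded genes were lower in all 6, with a median of -0.90 (camera adjusted p = 0.0197, and adjusted p = 0.964 with an estimated correlation) and 0 members at an unadjusted p under 0.05. That call was lost within the 15 libraries (-0.26, adjusted p = 0.34), with the deep batch as a covariate (-0.20, adjusted p = 0.364), with median-of-ratios scaling (-0.96, adjusted p = 0.0507), with the muscle marker covariates (-0.48, adjusted p = 0.225), without the 3 farthest libraries (-0.77, adjusted p = 0.0702) and without N1het healthy 3, 5 or 6 (-0.77, -0.65 and -0.72, adjusted p = 0.056, 0.092 and 0.0714), N1het healthy XCT790 1 (-0.41, adjusted p = 0.217), N1het stenosis 2 or 3 (-0.66 and -0.81, adjusted p = 0.21 and 0.0786) or N1het stenosis XCT790 2 (-0.39, adjusted p = 0.359). The number of genes called was 1 without N1het stenosis 1 and 2 without N1het stenosis XCT790 3, and 0 within the 15 libraries with 522 at an unadjusted p under 0.05.

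**Figure D3:**
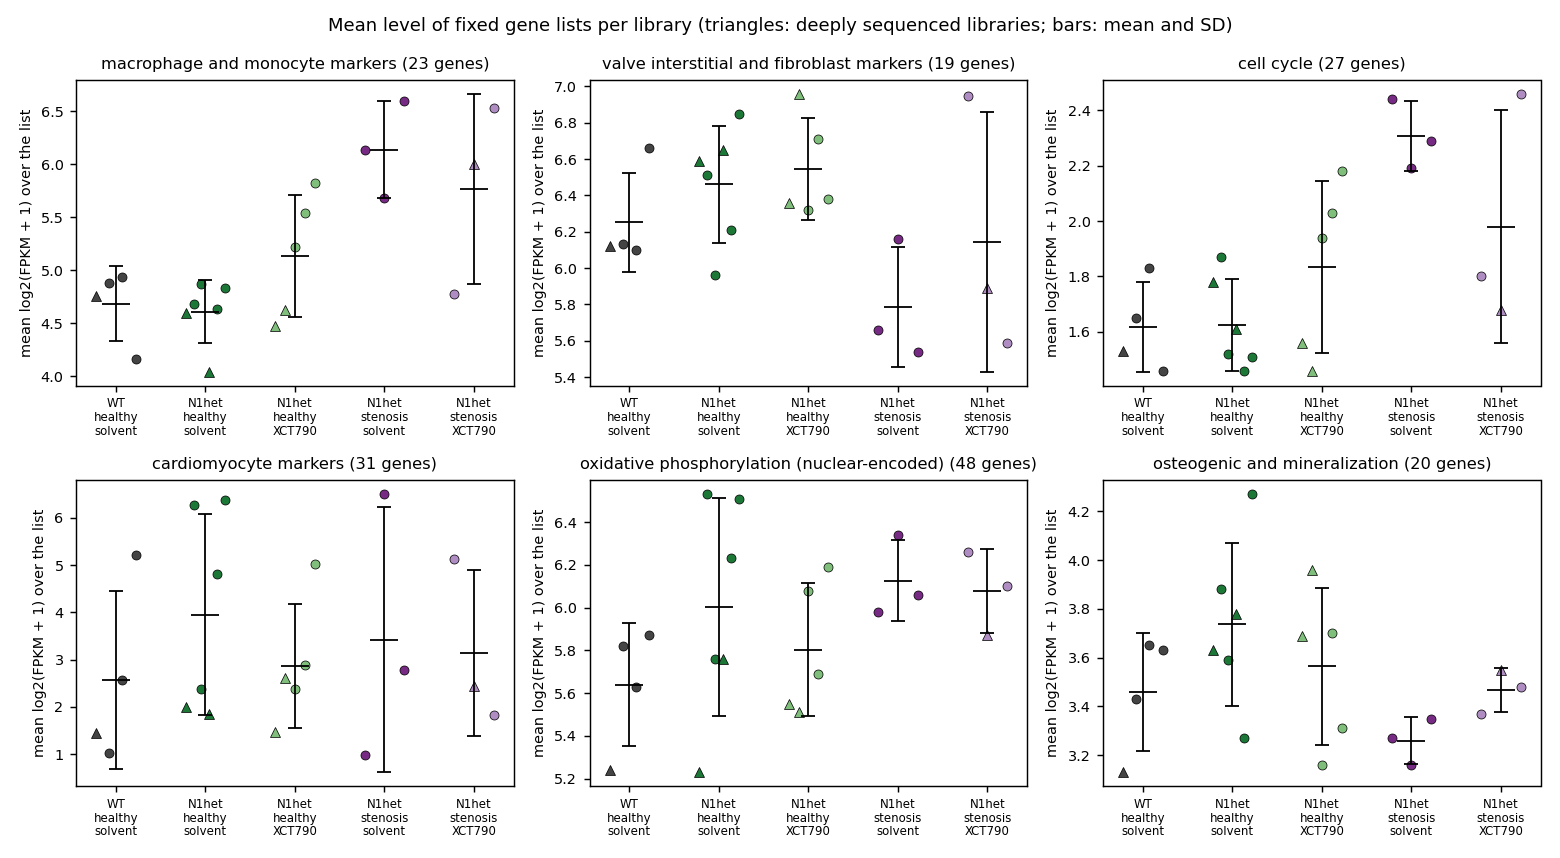
Each panel plots 1 list of marker or pathway genes, with the mean log2(FPKM + 1) of its tested members in each library on the y axis, the 5 groups on the x axis and bars at the mean and 1 SD. The 3 N1het stenosis libraries lie at 5.68 to 6.6 in macrophage and monocyte markers, above the 4 WT and 6 N1het healthy libraries at 4.04 to 4.94.

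In XCT790-treated N1het healthy against WT valves (n = 5 and 4), which joins genotype and compound, no gene passed. Acot7, a thioesterase gene of fatty acid metabolism, had 1.89 ± 0.34, Tmem97 2.50 ± 0.52, the serine synthesis gene Phgdh 2.37 ± 0.50, Zfp869 1.19 ± 0.24 and Grrp1 -3.43 ± 0.71, each with an adjusted p of 0.221, and the hormone gene Stc1 had -2.72 ± 0.71 (adjusted p = 0.373). Limma called 0 genes with 1107 at an unadjusted p under 0.05, and voom 0 with 1294. The median gene had a log2 difference of 0.12 in this contrast, which median-of-ratios scaling moved to 0.02. Endothelial markers were lower in 19 of 24, with a median of -0.45 (camera adjusted p = 0.000639, and adjusted p = 0.946 with an estimated correlation, exact permutation p = 0.0159 over the list's mean), and Emcn had -1.03 ± 0.47. Of these 24 genes limma called 0 over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, and the median was -0.48 within the 15 libraries. Mitochondrially encoded genes were lower in all 6, with a median of -1.82 (camera adjusted p = 0.00264, and adjusted p = 0.946 with an estimated correlation) and 0 members at an unadjusted p under 0.05. Their call was lost without WT 3 or 4 (medians -1.42 and -1.25, adjusted p = 0.0672 and 0.155) or N1het healthy XCT790 1 (-0.89, adjusted p = 0.232), without the 6 libraries with contradicting labels and with groups by the agent label (both -0.14, adjusted p = 0.8 and 0.81). The median was -1.14 within the 15 libraries. The number of genes called was 3 without WT 3, and 0 within the 15 libraries with 999 at an unadjusted p under 0.05.

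In XCT790-treated stenotic against WT valves (n = 3 and 4), no gene passed. Dgcr6 came closest (2.64 ± 0.44, adjusted p = 0.0865), followed by Lyz1 (3.83 ± 0.79), Nceh1 (1.89 ± 0.37), the interleukin subunit gene Ebi3 (3.37 ± 0.68) and the cartilage matrix gene Cilp (-2.90 ± 0.60), all with an adjusted p of 0.243. Mfap4 stood at 611 ± 95.8 FPKM in WT and 198 ± 122 in treated stenosis (-1.77 ± 0.42, adjusted p = 0.26). Limma called 0 genes with 1301 at an unadjusted p under 0.05, voom called 0 with 1503, and the count was 3 without N1het stenosis XCT790 1 or 3 and 0 within the 15 libraries with 1014. The median gene lay 0.17 above WT, or 0.05 above with median-of-ratios scaling. Ribosomal protein genes were higher in all 40, with a median of 0.42 (camera adjusted p = 6.68e-07, and adjusted p = 0.711 with an estimated correlation), and Rplp0 had 0.77 ± 0.22. Their median was 0.28 with median-of-ratios scaling. Macrophage markers were higher in 21 of 23, with a median of 0.99 (camera adjusted p = 4.93e-06, and adjusted p = 0.711 with an estimated correlation), with Ms4a7 at 2.28 ± 0.62. The macrophage call was lost without N1het stenosis XCT790 3 (median 0.50, adjusted p = 0.0713), and the median was 1.57 without N1het stenosis XCT790 1 and 0.60 within the 15 libraries. Over all genes limma called 0 members of both lists, with 12 and 10 at an unadjusted p under 0.05, and adjusted over the list alone 0 and 6 passed.

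To ask whether XCT790 moved genes back toward WT, its effect was correlated with the effect of disease or genotype across the 14966 genes, which are not independent replicates. Between pairs that share no library, r was 0.01 for XCT790 in healthy valves against stenosis over WT (permutation p = 0.848 over 462 splits) and 0.04 for XCT790 in stenotic valves against N1het healthy over WT (permutation p = 0.700 over 20 splits, which cannot give less than 0.1). Pairs that share their solvent libraries gave -0.38 in healthy valves and -0.49 in stenotic valves, where simulated groups with no effect gave -0.43 and -0.53. Their covariances were -0.105 beside -0.123 simulated, and -0.22 beside -0.239, and their permutation p was 0.413 and 0.350, the second with a smallest possible value of 0.05. Over the 4 pairs the adjusted permutation p was 0.826 or more. With the 6 solvent libraries of the healthy pair split into separate sets, 3 for each effect, r averaged 0.02 and ran from -0.04 to 0.09 over 20 splits, and the 3 solvent libraries of the stenotic pair are too few to split. Of the 5 genes called in stenosis against WT, 2 had the opposite sign with XCT790 in healthy valves.

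The deposited table carries the submitters' own marks of changed genes, 139 for N1het healthy and 281 for N1het stenosis against WT, 262 for stenosis against healthy N1het valves, 26 for XCT790 in healthy and 56 in stenotic valves. Of these, 93, 223, 217, 11 and 27 genes were tested here, and 74, 192, 195, 4 and 15 of them had an unadjusted p under 0.05. The marked genes came from these same libraries and are no independent evidence. All 5 genes called against WT and 4 of the 5 called against healthy N1het valves carry a mark.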

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

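The list tests with 1 library left out were chosen only after the result was seen. The values are of single libraries far from the rest of their group by Dixon's test, or of lists called in the XCT790 interaction. Of 387 groups of values tested, 28 held such a library, where chance gives about 1 in 20, here 19. N1het healthy 4 had 4, the most of any library.

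On the log2(FPKM + 1) scale, WT 1 stood apart with Cox6b1 at 4.97 (low) and Itgb2 at 4.35 (high), and with its 21.5 M reads, the highest of the WT libraries. WT 2 had Ptpn6 at 4.23 and Cdkn3 at 1.85, both high, and WT 3 Myl2 at 4.33, Aurkb at 1.42 and Ccl2 at 6.58, all high. WT 4 had Dct at 2.77 (low), Scamp4 at 2.35 (high) and a mean of fibroblast markers of 6.66 (high). Among N1het healthy libraries, number 1 had Cox6b1 at 5.89 (low), number 3 Esrra at 0.45 (low), Gja4 at 6.64 (high) and Fcgr1 at 0.96 (low), and number 4 Pdgfra at 4.65 (low), Ctss at 5.35 (low), Efna2 at 1.49 (high) and a mean of macrophage markers of 4.04 (low). Number 5 had Bst2 at 6.54 (high), and number 6 Myh11 at 5.11 (high) and H2-Aa at 7.62 (low). Among N1het healthy XCT790 libraries, number 1 had S100a9 at 0.11 (high), number 2 Dct at 5.59 (low) and Bst2 at 4.96 (low), number 3 Msx1 at 4.13 (low), and number 5 Cog7 at 1.62 (low) and Ckmt2 at 2.42 (high). Groups of 3 libraries were not tested this way.

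The XCT790 interaction (camera) shares solvent libraries with stenosis against healthy valves. Its median log2 difference was -0.78 for macrophage markers, -1.95 for neutrophil and mast cell markers, -0.4 for cell cycle and -0.42 for antigen presentation. With an estimated correlation the adjusted p was 0.547 for the first 3 and 0.937 for antigen presentation. Neutrophil and mast cell markers were lower in all 9 genes (camera adjusted p = 0.000261), with a median of -1 without N1het healthy XCT790 4 and -0.87 without N1het stenosis 2. S100a9 had an interaction of -2.73 ± 1.03 and S100a8 of -2.32 ± 1.11. Antigen presentation genes (camera adjusted p = 0.0291) lost the call without N1het healthy 3 (-0.35, adjusted p = 0.0531), N1het healthy 6 (-0.37, 0.0527), N1het healthy XCT790 3 (-0.37, 0.0515), N1het healthy XCT790 5 (-0.20, 0.286), N1het stenosis 3 (-0.18, 0.689) or N1het stenosis XCT790 1 (-0.11, 0.799), without the 3 libraries farthest from the rest (-0.35, 0.0602) and with no filter on low values (0.0523). Their median was -0.66 without N1het stenosis 2, -0.68 with the muscle marker covariates and -0.80 within the 15 libraries outside the deep batch.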

How the results depend on the processing

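Tests chosen only after the data were seen were voom without weights, the deep batch as a covariate, the 15 libraries outside that batch, the fit without the 3 libraries farthest from the rest (WT 1, WT 4 and N1het healthy 3), the rescaling to reads that are not mitochondrial, the covariates of 1 cell type alone the list tests with 1 library left out, and those with other filters, upper-quartile scaling, a pseudocount of 0.1 or the agent labels. No result changed its direction past the threshold under an alternative run on it, and the lists were not tested by voom or with only the compared groups: of the counts, list tests and correlations, 316 of the values under other settings stayed on their side of the threshold or within 1.5 times, 32 were weaker, 30 stronger and 1 moved, and for single genes 17601 stayed, 100 were weaker, 71 stronger and 87 moved, left-out libraries included. Only a called gene can be weaker, and most single-gene values that stayed are of genes never called, so these totals do not measure how stable the calls are. Of 15 other settings, the called genes passed in 7 (Nppb, Nceh1 and BC067068 against WT) to 13 (Rara against healthy N1het valves). The spread between libraries limits single genes, since a 2-fold change was recovered in 7.46% of simulated genes for stenosis against healthy N1het valves, and in 65.7% with a spread 10 times smaller. The cause of a change was not tested except where fewer libraries or genes entered the fit. No count model or sex covariate was run, the table holding FPKM and 1 sex. The agent label served only where it leaves 2 groups.

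Genes called in stenosis against WT, 5 by the main test, were 11 at an adjusted p under 0.1, 8 with the filter by CPM, 9 with median-of-ratios scaling, 3 by voom, 1 by voom with sample quality weights, 1 without the 3 farthest libraries, and 0 with muscle marker covariates (1252 at an unadjusted p under 0.05), with the deep batch as a covariate (1443), with only the compared groups (1166) and in the 15 libraries (1320). In stenosis against healthy N1het valves, also 5, they were 8 at an adjusted p under 0.1, 23 with muscle marker covariates, 22 by voom with weights, 14 with only the compared groups, 16 without the 3 farthest libraries, and 0 by voom (1326) and in the 15 libraries (1105). Contrasts with 0 calls by limma gave a few. The contradicting agent label as grouping gave 1 for N1het healthy against WT, 1 for XCT790 in healthy valves and 18 for treated stenosis against WT. Treated stenosis against WT also gave 1 at an adjusted p under 0.1, 3 with the filter by CPM, 3 without a filter and 7 with the deep batch as a covariate. The averaged effect of XCT790 gave 1 with the filter by CPM and 1 without a filter, and XCT790 in stenotic valves 2 and 2.

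With the replicate number as a block, 3 genes were called in stenosis against WT and 19 in stenosis against healthy N1het valves. The numbers do not pair the libraries: over 25 pairs with the same number in 2 groups, deviations from the group means correlated at -0.109 to 0.13, 3 were over 0.1, and 9 were the highest for their library. No other count of genes and no count of lists left its 1.5-fold range under the block, though for N1het healthy against WT only 3 of the 8 lists it called were among the 8 called without it.

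Lists called by camera numbered 8 for N1het healthy against WT, 9 and 16 for stenosis against WT and against healthy N1het valves, 11 and 3 for XCT790 in healthy and stenotic valves, 4 for the interaction, 6 for the averaged effect, and 3 and 10 for treated healthy and treated stenotic valves against WT. With an estimated correlation each of the 9 numbers was 0, and with fry it was 0 except 3 for stenosis against healthy N1het valves. In the 15 libraries treated healthy valves had 8, stenosis against healthy 10, XCT790 in stenotic valves 5 and the interaction 8. With muscle marker covariates N1het healthy against WT had 13, treated stenosis 6 and the interaction 9, and the lists also called without them were 1 of the 13 for N1het healthy against WT, 5 of 12 for XCT790 in healthy valves and 0 of 5 for the averaged effect. With the deep batch as a covariate XCT790 in stenotic valves had 7 and the interaction 8. Without the 3 farthest libraries N1het healthy had 16 and treated stenosis 6. With groups by the agent label N1het healthy had 1 and treated healthy valves 5, and without the 6 contradicting libraries treated healthy valves had 7. For XCT790 in healthy valves these 2 settings called 13 lists each, of which 4 and 6 were among the 11. The correlation of the effect of XCT790 in healthy valves with that of N1het over WT, -0.38, was 0.02 once separate solvent libraries entered each effect.

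Leaving out 1 library at a time gave 0 to 3 genes in stenosis against WT, 2 to 11 in stenosis against healthy N1het valves, 0 to 5 in N1het healthy against WT, 0 to 3 in treated healthy and in treated stenotic valves against WT, and 0 to 2 in XCT790 in stenotic valves, the interaction and the averaged effect. Called lists ran from 3 to 13 in N1het healthy against WT, 8 to 14 in stenosis against WT, 1 to 6 and 4 to 13 in treated healthy and treated stenotic valves against WT, 1 to 11 in the averaged effect, 1 to 10 in XCT790 in stenotic valves and 3 to 9 in the interaction. The correlation with stenosis over WT of XCT790 in healthy valves ran from -0.04 to 0.06, and that with N1het over WT of XCT790 in stenotic valves from -0.01 to 0.06.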

Other observations

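The tests of blood and of a lower fibroblast share were chosen only after the result was seen, as were the comparisons within the 15 libraries outside the deep batch and those with a covariate of 1 cell type alone.

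Wnt response genes were lower in stenotic than in healthy N1het valves in 19 of 23, with a median log2 difference of -0.47 (camera adjusted p = 0.002, and adjusted p = 0.291 with an estimated correlation). Dkk3 had -0.90 ± 0.27 and the transcription factor gene Lef1 -1.89 ± 0.58. Adjusted over the list alone 2 passed, against 0 over all genes tested by limma, with 8 at an unadjusted p under 0.05. The median was -0.86 without N1het stenosis 1, -0.29 without N1het stenosis 3 and -0.82 with a pseudocount of 0.1, and the call was lost within the 15 libraries (-0.33, adjusted p = 0.0608). Lymphocyte markers were higher in 8 of 9, with a median of 0.73 (camera adjusted p = 0.000667, and adjusted p = 0.189 with an estimated correlation), among them Cd52 at 1.97 ± 0.55 and the pan-leukocyte gene Ptprc at 1.43 ± 0.47. Of these 9 genes 3 passed adjusted over the list alone and 0 over all genes, with 4 at an unadjusted p under 0.05. Their median was 1.18 without N1het healthy 1, 1.33, 1.27 and 0.33 without N1het stenosis 1, 2 and 3, 1.52 with a pseudocount of 0.1, and 1.17 within the 15 libraries or with the deep batch as a covariate.

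Melanocyte markers, pigment cells being residents of mouse valves, were higher than in WT in 3 N1het groups: in 10 of 11 genes in N1het healthy valves (median 0.93, camera adjusted p = 0.0447, and adjusted p = 0.785 with an estimated correlation), in 10 of 11 in stenosis (median 1.03, camera adjusted p = 0.0162, and adjusted p = 0.68 with an estimated correlation) and in all 11 in treated healthy valves (median 0.99, camera adjusted p = 0.00264, and adjusted p = 0.946 with an estimated correlation). The pigment enzyme gene Dct had 1.77 ± 0.85 in stenosis and the neural crest factor gene Sox10 2.09 ± 0.63 in treated healthy valves. They did not pass in treated stenosis against WT (median 1.285, adjusted p = 0.0597), in stenosis against healthy N1het valves (0.29, adjusted p = 0.46) or with XCT790 in healthy valves (0.41, adjusted p = 0.174). Limma called 0 members over all genes in the 3 contrasts, with 0, 2 and 1 at an unadjusted p under 0.05, and 0, 0 and 1 adjusted over the list alone. The call in N1het healthy valves was lost without WT 2 or 4 (0.88 and -0.01, adjusted p = 0.0597 and 0.717), N1het healthy 3, 4 or 6 (0.75, 0.84 and 0.72, adjusted p = 0.146, 0.1 and 0.106) or the 3 libraries farthest from the rest (0.23, 0.649), with muscle marker covariates (0.49, 0.65), with the deep batch as a covariate (0.052), with groups by the agent label (0.072) and without the 6 contradicting libraries (0.0524). The stenosis call was lost without N1het stenosis 3 (0.96, adjusted p = 0.128) or WT 4 (0.82, 0.258) and without the 3 farthest libraries (0.69, 0.0718), with a median of 0.68 without WT 2 and 1.62 with a pseudocount of 0.1. In treated healthy valves it was lost without N1het healthy XCT790 4 (0.79, 0.179) or WT 4 (0.42, 0.225) and without the 3 farthest libraries (0.62, 0.112), with a median of 1.63 without WT 1, 1.53 with a pseudocount of 0.1, 1.7 without the 6 contradicting libraries or with groups by the agent label, and 2.00 within the 15 libraries.

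Macrophage markers higher in stenotic than in healthy N1het valves may reflect more macrophages in the diseased valve, which is a hypothesis, since cell numbers were not measured here. Depth and mitochondrial share are argued against as the whole cause, because the median within the 15 libraries was 1.36 (camera adjusted p = 2.39e-19), 90.3% of the value over all libraries. Blood left in the tissue would raise red cell and platelet markers as well, and their median was -0.49, below the macrophage median by 1.22 to 2.31 with any 1 compared library left out. A lower share of fibroblasts would raise the markers of every other cell type alike, but the highest median among endothelial, smooth muscle and melanocyte markers was 0.29, below the macrophage median by 0.8 to 1.31. Higher output per macrophage and, by the agent label, XCT790 stay open. With an estimated correlation the list missed the threshold (adjusted p = 0.0601).

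Oxidative phosphorylation genes lower with XCT790 in healthy N1het valves are what a block of ERRα could give, but heart muscle in the samples gives the same. With the heart muscle marker level as a covariate the median went from -0.23 to -0.06 (camera adjusted p = 0.253), so a smaller amount of heart muscle in the treated samples is a candidate explanation. The call ended because the median shrank to 25% of its value, nearer to 0 than any value in the range of -0.38 to -0.12 with 1 compared library left out. Depth and mitochondrial share are argued against, since the median was -0.27 within the 15 libraries (camera adjusted p = 3.66e-05). The effect of the compound itself stays open, and the median was -0.02 (adjusted p = 0.614) without the 6 libraries with contradicting labels.

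Osteogenic genes lower in stenotic than in healthy N1het valves go against the bone-like program that calcifying valves can take on, though the list did not pass against WT (adjusted p = 0.269). A lower level of fibroblast markers was tested as the cause, and with that level as a covariate the median was -0.56 where it had been -0.52, with a camera adjusted p of 0.0493 that lies close to the threshold. Over left-out libraries the median without the covariate ran from -0.69 to -0.47. Depth and mitochondrial share could not be told apart from the difference, because within the 15 libraries the median was -0.59 but the adjusted p 0.0608. Disease or, by the agent label, XCT790 stays open as the source, and the labels give no stage.

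Other splits of the same libraries into groups of the same sizes, the real split included, show how often chance gives as many genes. Their shares are not adjusted over the contrasts. In stenosis against healthy N1het valves 2 of 84 splits gave as many genes at an unadjusted p under 0.05. The real split had 1437 and the highest other 1510. As many called genes came from 2 of 84 splits, with 5 in the real split and 20 in the highest other. Both shares lie under 0.05, but they are unadjusted and another split gave more genes each time, so chance is not excluded. The split with 20 called genes exchanges N1het healthy 2 and 6 with N1het stenosis 1 and 3, and so sets N1het healthy 2 and 6 and N1het stenosis 2, which are 3 of the 4 libraries of this contrast with heart muscle markers at 4.82 or more, against the rest. With the muscle marker covariates the real split gave 23. In stenosis against WT 1 of 35 splits gave as many called genes (5, highest other 4), the smallest share that 35 splits can give. At an unadjusted p under 0.05, 2 of 35 gave as many (1563, highest other 1661), a share over 0.05, so chance is not excluded for this count. Chance was not excluded for genes at an unadjusted p under 0.05 in N1het healthy against WT (14 of 100 splits, 1111, highest other 1708), in treated healthy valves against WT (12 of 100, 1107, highest other 1343), in treated stenosis against WT (4 of 35, 1301, highest other 1500), for XCT790 in healthy valves (96 of 100, 397, highest other 1413), for the interaction (83 of 100, 446, highest other 1047) and for the averaged effect (71 of 100, 482, highest other 1493). The highest split for XCT790 in healthy valves exchanges N1het healthy 1, 3 and 4 with N1het healthy XCT790 3, 4 and 5, which partly follows the deep batch, and within the 15 libraries the real split gave 713. XCT790 in stenotic valves has 10 splits, too few for a share under 0.05, and 7 of them gave as many genes, with 501 in the real split and 974 in the highest other.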
